A study of Mus musculus with 6 samples.

How the data were processed

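Gene expression was measured in primary mouse astrocyte cultures from the cortex and striatum of newborn C57BL/6J pups, with 6 one-colour Agilent arrays in 3 groups of 2. Per the labels, control cultures were kept in medium with 10% serum (the protocol text speaks of an equivalent amount of DMSO), Ro cultures received 1 µM of the GSK-3 inhibitor Ro3303544 for 48 h, and washout cultures received it for 48 h and were then kept for 48 h without it. Treatment began at 13 days in vitro, after 2 days with 5 µM AraC, an inhibitor of DNA synthesis that removes dividing cells. Per the labels fewer than 1% of the cells carried the microglial protein Iba1, and RNA had an integrity number of at least 6.5. The labels do not say whether the 2 cultures of a group came from separate preparations.

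The deposited array files hold intensity values on a linear scale for each spot. The authors labelled the RNA with Cy3 and extracted the scans with Agilent Feature Extraction, version 10.1 by their notes and 10.5.1.1 by the file headers. The processed intensity had been corrected for background within each array and not scaled between arrays. The deposited table of all samples holds a linear ratio for each probe, centred per probe by a rule that the authors did not state. Its probe-centred log2 values correlated across probes with those of the processed intensity at r = 0.993 or above on every array, and it served as an alternative only.

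Of 41174 non-control probes, 106 were left out for spots marked as faulty. The log2 processed intensity was reduced by each array's 75th percentile. A probe was kept when Feature Extraction called it well above background on both arrays of at least 1 group, which left 26475 probes. Probes were named through their accession and the reference table, which has no coordinates, so that no genome positions are given. A symbol was found for 25097 of all 41174 non-control probes (61.0%), and kept probes without one were tested under their accession and not named. For each gene the probe with the highest mean was used, giving 20092 features, 13053 of them with a symbol.

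Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 6 arrays and moderated two-sided tests (3 residual and 2.07 prior degrees of freedom). Benjamini-Hochberg adjusted p under 0.05 was the threshold. Changes are differences of group means on the log2 scale ± the standard error from limma, with 2 arrays per group. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so that every call rests on the spread pooled by limma. Where no probe of a gene was well above background on either array of 1 group, its change is given as a lower bound. The bound was computed from the lowest signal called above background and used only where it kept the direction of the change. In total 37 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists within a comparison. Camera at an estimated correlation relies on the 3 residual degrees of freedom, so that few lists could pass it at any correlation. Failing it therefore does not by itself show that a call came from correlation between genes. The estimated correlation was 0.0043 for Wnt targets, below the preset. Among lists with a call it was highest for ependymal markers (0.677), ribosomal protein (0.508), interferon response (0.455), microglia (0.442) and oxidative phosphorylation genes (0.424). At such correlations the preset test gives too small a p, so that these calls may rest in part on correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

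The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took 8 fixed genes, the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups' arrays, up to 5 bounds per direction, and up to 4 members of each list. Alternatives changed the background correction, scaling, filter, variance model, choice of probe, arrays in the fit, pairing and fold minimum, and left out each array in turn. A planned background correction needed a mean spot signal that the files lack and was not run. A version on the median signal, an exchanged pairing of the Ro arrays, and a fit without probes in bright regions of the slides were chosen after seeing the data.

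The procedure was tested on simulated data with the gene means of the arrays and independent normal noise at the spread that limma estimated per gene. Correlation between genes, a slide difference and the bright regions were not simulated, so that the draws do not cover them. With 200 of 20092 genes changed in Ro, none of the 1.5-fold changes were recovered, 78.2% of 2-fold changes were recovered with 6.21% false calls, and 95.7% of 4-fold changes with 5.35% false calls, as means of 20 draws. With 5023 genes changed 2-fold, 94.9% were recovered with 3.64% false calls. The number of draws was raised to 20 after single draws of the 2-fold case had given different shares of false calls; over the 20 draws this share lay between 2.45% and 9.30%. With no change, 0 of 20 draws gave a call for Ro minus control, 2 of 20 for washout minus Ro (at most 2 calls) and 1 of 20 for washout minus control (1 call).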

Results

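The data are 6 arrays, 2 each for control cultures, cultures treated with the GSK-3 inhibitor Ro3303544 (Ro), and cultures washed out after treatment (washout). Between 60.4% and 65.2% of the probes were well above background on each array, and the 75th percentile of the processed intensity lay between 629 and 804. The number of arrays limits the precision. Replicates correlated across the features tested at r = 0.995 in control, 0.996 in Ro and 0.992 in washout. Between control and Ro arrays r was 0.963 to 0.966, and between control and washout arrays 0.984 to 0.985. The control and Ro arrays shared 1 slide and the washout arrays lay on another, so that washout and slide cannot be told apart for a single gene. Washout cultures were harvested at 17 days in vitro and the others at 15, with no control of the same age. Dim spots were raised in a streak on the washout slide, called bright regions here, which covered 3.84% of the spots of washout 1 and 0.837% of washout 2.

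**Figure D1:**
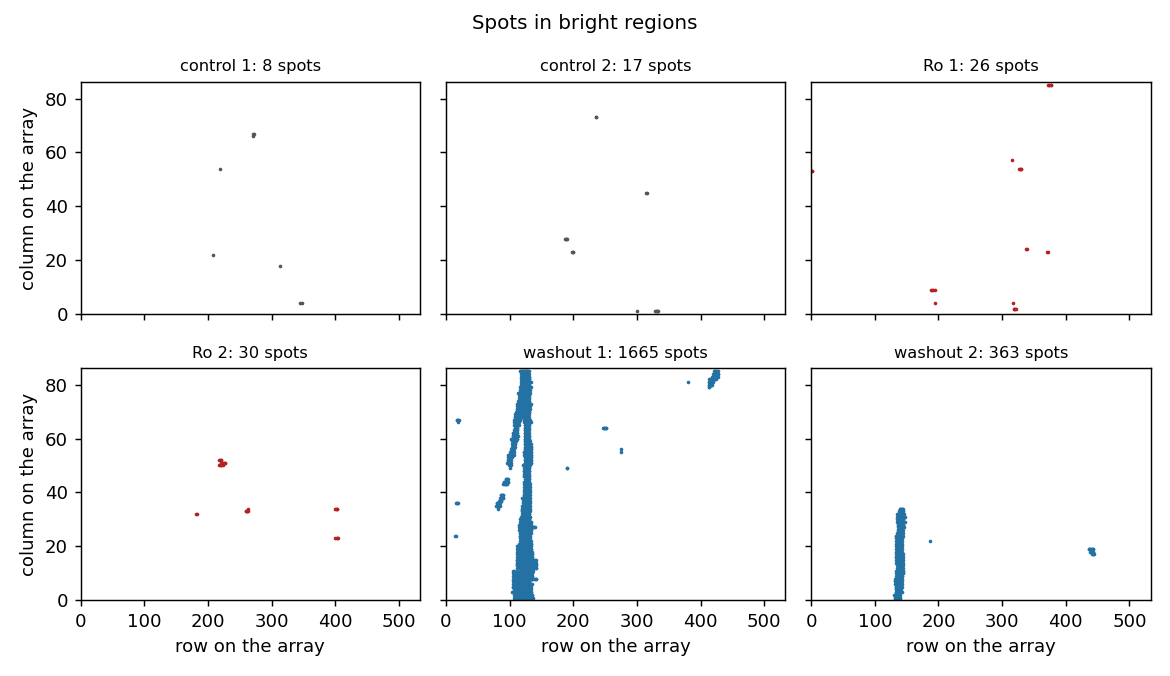
Row and column on the array of each spot in a bright region, 1 panel per array, with colours for groups. Washout 1 had 1665 such spots and washout 2 had 363, against 8 to 30 on the control and Ro arrays.

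The comparison of Ro with control asked how sustained inhibition of GSK-3, a kinase that marks beta-catenin for destruction, changed astrocyte expression. Targets of the Wnt/beta-catenin pathway rose. Sp5, a transcription factor induced by Wnt, rose by 8.23 ± 0.08 on the log2 scale (300-fold, adjusted p = 1.9e-05). The feedback inhibitors Rnf43, Notum and Nkd1 rose by 5.98 ± 0.13, 5.96 ± 0.11 and 5.63 ± 0.07, and Axin2, a scaffold of the complex that degrades beta-catenin, by 4.29 ± 0.13 (adjusted p = 0.00010). Of 19 measured Wnt targets 15 rose and 2 fell, with the same counts adjusted over the list alone, and the list passed the test (mean 3.17, adjusted p = 1.2e-07). The list was not past the threshold with an estimated correlation (adjusted p = 0.331 with an estimated correlation). The 2 that fell were the growth regulator Myc (-1.15) and the morphogen Bmp4 (-1.07), named after their values were seen. Transcripts of Gsk3a (0.17 ± 0.12), Gsk3b (0.06 ± 0.15) and Ctnnb1 (0.16 ± 0.07), which encode both forms of the kinase and beta-catenin, did not pass the test, and the mean of its probes put Gsk3b at -0.040.

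**Figure D2:**
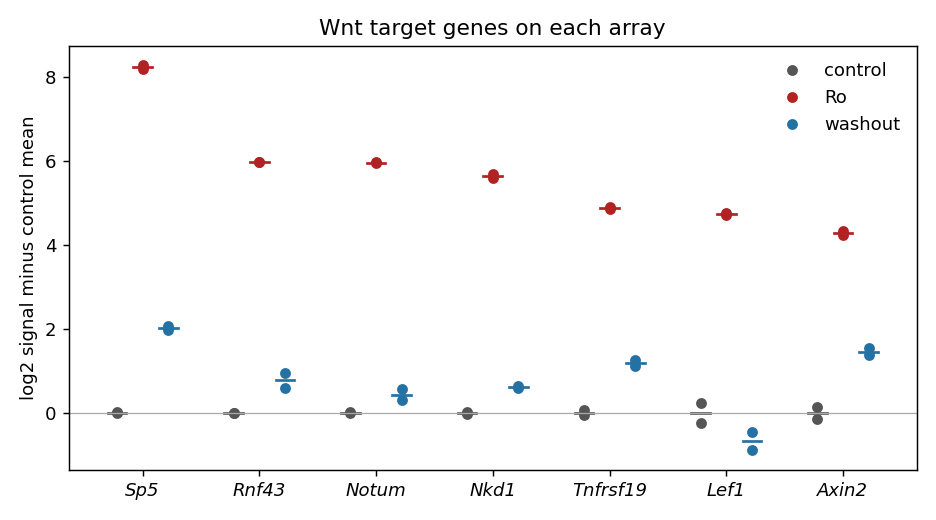
Log2 signal of 7 Wnt target genes on each array minus the control mean of the gene; points are arrays, short bars are group means of 2 arrays, and colours are groups. Sp5 lay 8.23 above control in Ro and 2.02 above control in washout.

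Other large rises were those of Dapk2, a kinase linked to cell death, at 6.15 ± 0.07, Dio2, which activates thyroid hormone, at 5.34 ± 0.11, and Slc7a11, the cystine transporter, at 5.06 ± 0.23. The BMP antagonist Grem1 was at least 52.4-fold higher. The neuropeptide gene Npvf fell by 4.35 ± 0.12, the cartilage matrix gene Cnmd by 4.27 ± 0.09, and the granin Chgb changed by -3.40 ± 0.08.

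The lists of SRF and YAP targets, integrin and focal adhesion genes and extracellular matrix genes passed the test as falls. Cadherin and cell junction genes did not pass (mean -0.10, adjusted p = 0.230), with 6 of 15 lower and 2 higher, also adjusted over the list alone. All 14 measured targets of SRF and YAP, factors that respond to actin and tension, fell, as they did adjusted over the list alone (mean -1.19, adjusted p = 1.1e-07; adjusted p = 0.403 with an estimated correlation). Among them were Ccn2, a matricellular protein, at -2.08 ± 0.08 and Cnn1, a smooth muscle calponin, at -1.89 ± 0.09. Acta2, smooth muscle actin, fell by 1.76 ± 0.08, on a probe in a bright region of at least 1 of the 6 arrays. The other Acta2 probes gave -2.23 and -1.30. Pericytes and smooth muscle cells express several of these SRF and YAP targets. Of 8 markers of these cells 6 fell and 1 rose, also adjusted over the list alone (mean -0.76, adjusted p = 0.0093; adjusted p = 0.494 with an estimated correlation), with Acta2 in both lists and Cspg4 also among the oligodendrocyte precursor markers. Of 29 integrin and focal adhesion genes 18 fell and 2 rose, with the same counts adjusted over the list alone (mean -0.61, adjusted p = 4.1e-05; adjusted p = 0.603 with an estimated correlation). The collagen receptor subunits Itga11 and Itga1 fell by 2.75 ± 0.19 and 1.39 ± 0.07. Itga8 (0.66) and Itga9 (0.59), named after their values were seen, were the 2 that rose. Of 30 extracellular matrix genes 13 fell and 4 rose, also adjusted over the list alone (mean -0.32, adjusted p = 0.047; adjusted p = 0.662 with an estimated correlation), and this call was lost without control 2 (adjusted p = 0.083) and without Ro 1 (adjusted p = 0.051). Nid2, a basement membrane linker, fell by 1.89 ± 0.07, while Lama4, a laminin chain, rose by 3.95 ± 0.07.

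The lists of ribosomal protein, cholesterol synthesis and oxidative phosphorylation genes passed the test as rises. Of 20 ribosomal protein genes 19 rose, and 20 adjusted over the list alone (mean 0.60, adjusted p = 4.6e-07; adjusted p = 0.603 with an estimated correlation), with Rps6 at 0.86 ± 0.08 and Rpl10 at 0.80 ± 0.11. Of 24 cholesterol synthesis genes 16 rose and none fell, and 16 rose and 1 fell adjusted over the list alone (mean 0.41, adjusted p = 0.00020; adjusted p = 0.403 with an estimated correlation). The sterol enzymes Msmo1 and Mvd rose by 0.93 ± 0.09 and 0.77 ± 0.10. Of 22 oxidative phosphorylation genes 9 rose, also adjusted over the list alone (mean 0.24, adjusted p = 0.0049; adjusted p = 0.662 with an estimated correlation).

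Interferon response genes fell, 14 of 18 measured, also adjusted over the list alone (mean -0.87, adjusted p = 3.9e-05; adjusted p = 0.613 with an estimated correlation), with Ifit1 at -1.84 ± 0.29 and Isg15 at -1.54 ± 0.19, both antiviral effectors. Of 19 markers of microglia, cells that also express interferon genes, 8 fell and 3 rose, and 9 fell and 3 rose adjusted over the list alone (mean -0.35, adjusted p = 0.028; adjusted p = 0.662 with an estimated correlation). The microglia call was lost without control 1 (adjusted p = 0.108) and without Ro 1 (adjusted p = 0.078). The receptors Cx3cr1 and Csf1r fell by 1.76 ± 0.22 and 1.26 ± 0.13.

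Ependymal and oligodendrocyte precursor markers were also lower, while the lists for oligodendrocytes (adjusted p = 0.751), neurons (adjusted p = 0.414), endothelial cells (adjusted p = 0.612) and meningeal fibroblasts (adjusted p = 0.398) did not pass. All 9 ependymal markers fell, as they did adjusted over the list alone (mean -1.56, adjusted p = 1.9e-05; adjusted p = 0.603 with an estimated correlation), including Ccdc153 at -2.68 ± 0.11 and Dynlrb2, a dynein light chain, at -1.85 ± 0.11. Of 7 oligodendrocyte precursor markers 6 fell, and 7 adjusted over the list alone (mean -1.32, adjusted p = 0.00026; adjusted p = 0.403 with an estimated correlation), with the lineage factors Olig1 and Olig2 at -2.05 ± 0.07 and -2.04 ± 0.07. Of 18 growth factor and IGF-binding genes 8 fell and 3 rose, and 10 fell and 3 rose adjusted over the list alone (mean -0.59, adjusted p = 0.041; adjusted p = 0.630 with an estimated correlation), a call lost with the mean of a gene's probes (adjusted p = 0.068), without bright regions (adjusted p = 0.059) and without control 2 (adjusted p = 0.061).

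Astrocyte genes went both ways. The glutamate transporter Slc1a2 rose by 1.21 ± 0.10 (adjusted p = 0.0011) and the gap junction gene Gjb6 by 3.45 ± 0.15, while the intermediate filament gene Gfap fell by 0.98 ± 0.09 (adjusted p = 0.0012) and the water channel gene Aqp4 by 1.87 ± 0.15. Vim (-0.26 ± 0.15) and Slc1a3 (0.06 ± 0.10), an intermediate filament and a glutamate transporter, did not pass the test, and quantile normalization put Slc1a3 at -0.028. Of 24 mature astrocyte genes 5 rose and 13 fell, and 6 rose and 14 fell adjusted over the list alone, and the list was not past the threshold (adjusted p = 0.179). Among lists that did not pass, mean and test differed in sign for Wnt pathway components, matrix proteases, BMP and TGF-beta genes, inflammatory genes and unfolded protein response genes, and mean and median for immediate early genes.

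In limma, 3906 of 20092 features were higher in Ro and 4581 lower (42.2% of features), 865 and 1398 of them at least 2-fold. Of the calls 46.0% were higher, against 51.4% with median centring and 51.3% with the authors' values, so that which direction had more calls depended on the scaling. The 4 arrays of the shared slide alone gave 4137 higher and 4735 lower, and with no filter on dim probes 2497 were higher. Without control 1, control 2, Ro 1 or Ro 2 the counts were 2322, 2540, 1962 and 2061 higher, and without Ro 1 or Ro 2 they were 2672 and 2715 lower. Of the 37 lists 14 passed with the preset correlation and none with an estimated correlation, and fry called 28.

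**Figure D3:**
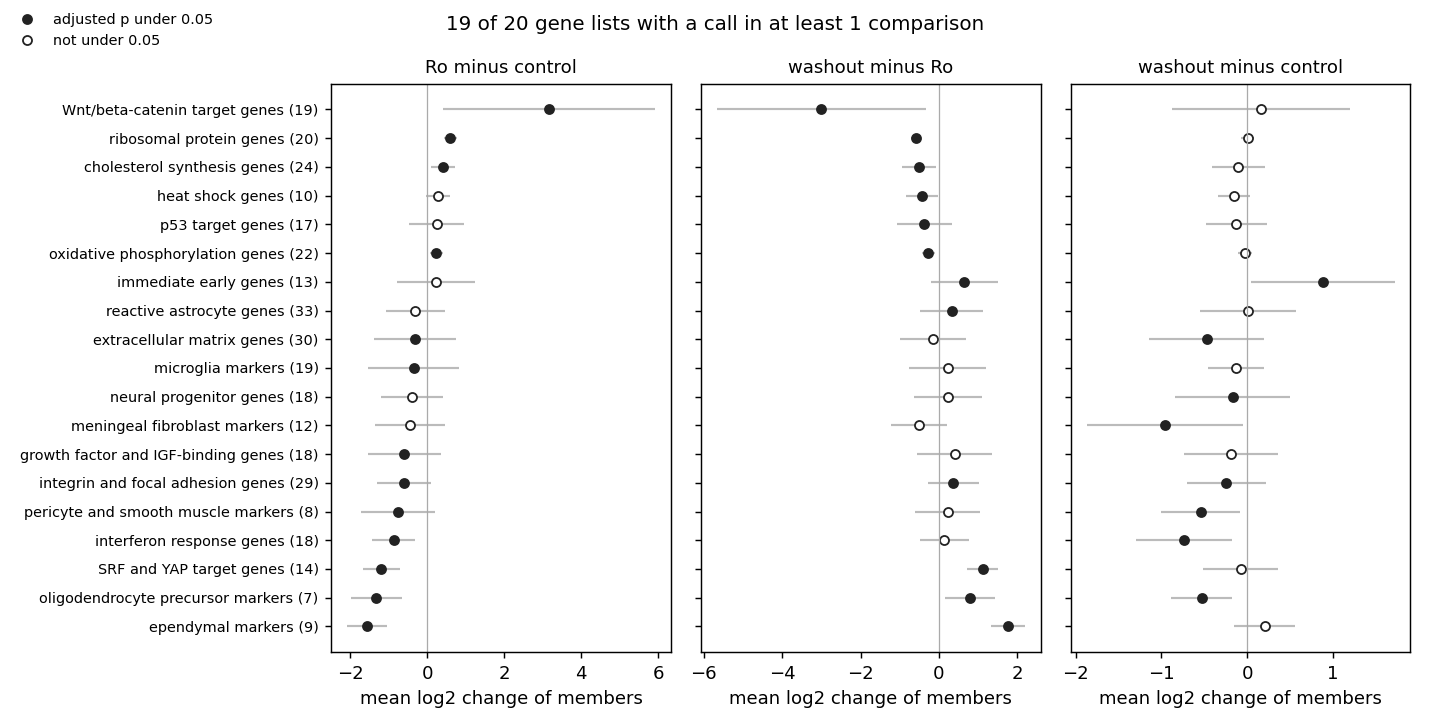
Mean log2 change of the members of 19 of the 20 gene lists with a call in at least 1 comparison, with the number measured in brackets; grey lines are 1 SD of the members, filled points had adjusted p under 0.05 with the preset correlation. None of these calls held with an estimated correlation, a test that relies on 3 residual degrees of freedom.

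The comparison of washout with Ro asked what happened when the inhibitor was removed. No cultures were kept with Ro over the same time, so that removal and time since the start of treatment cannot be told apart. Wnt targets fell: Sp5 changed by -6.21 ± 0.08, Notum by -5.52 ± 0.11, the transcription factor Lef1 by -5.40 ± 0.21 and Axin2 by -2.83 ± 0.13, and the secreted Wnt inhibitor Wif1 was at least 48.3-fold lower. Of 19 Wnt targets 16 fell and 2 rose, also adjusted over the list alone (mean -3.00, adjusted p = 1.0e-07; adjusted p = 0.327 with an estimated correlation); the 2 were Myc (1.64) and Bmp4 (0.73). All 14 SRF and YAP targets rose, also adjusted over the list alone (mean 1.12, adjusted p = 1.0e-07; adjusted p = 0.401 with an estimated correlation), with Ccn2 at 1.68 ± 0.08 and Cnn1 at 1.63 ± 0.09. Of 29 integrin and focal adhesion genes 18 rose and 2 fell, and 18 rose and 3 fell adjusted over the list alone (mean 0.36, adjusted p = 0.0036; adjusted p = 0.677 with an estimated correlation).

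All 9 ependymal markers rose, also adjusted over the list alone (mean 1.77, adjusted p = 4.2e-06; adjusted p = 0.603 with an estimated correlation), with Ccdc153 at 2.35 ± 0.11. Of 7 oligodendrocyte precursor markers 5 rose, also adjusted over the list alone (mean 0.79, adjusted p = 0.0080; adjusted p = 0.411 with an estimated correlation), a call lost with no filter (adjusted p = 0.051). All 20 ribosomal protein genes fell, also adjusted over the list alone (mean -0.59, adjusted p = 1.2e-06; adjusted p = 0.638 with an estimated correlation). Of 24 cholesterol synthesis genes 15 fell and 1 rose, and 18 fell and 1 rose adjusted over the list alone (mean -0.51, adjusted p = 8.5e-05; adjusted p = 0.401 with an estimated correlation). Of 13 immediate early genes 9 rose and 2 fell, also adjusted over the list alone (mean 0.65, adjusted p = 0.0050; adjusted p = 0.401 with an estimated correlation), with the phosphatase gene Dusp1 at 1.99 ± 0.08. Of 17 p53 targets 9 fell and 2 rose, and 13 fell and 2 rose adjusted over the list alone (mean -0.37, adjusted p = 0.00997; adjusted p = 0.603 with an estimated correlation). Of 22 oxidative phosphorylation genes 7 fell, also adjusted over the list alone (mean -0.27, adjusted p = 0.0036; adjusted p = 0.677 with an estimated correlation). The remaining calls, for reactive astrocyte genes (mean 0.32, adjusted p = 0.045; adjusted p = 0.603 with an estimated correlation) and heat shock genes (mean -0.43, adjusted p = 0.022; adjusted p = 0.603 with an estimated correlation), were each lost under several alternatives. Gfap rose by 1.04 ± 0.09 and Slc1a2 fell by 1.01 ± 0.10.

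In limma 4283 features were higher in washout than in Ro and 4075 lower, 1323 and 989 of them at least 2-fold. Of the calls 51.2% were higher, against 40.5% with median centring and 38.9% with the authors' values, which moved the median of all features to -0.11 and -0.12. Without Ro 1 or Ro 2 the counts were 2624 and 2647 higher, and 2257 and 2230 lower. With no filter on dim probes 2699 were lower. Among lists that did not pass, mean and test differed in sign for Wnt pathway components, cell junction genes and BMP and TGF-beta genes, and mean and median for inflammatory, glycolysis and oligodendrocyte genes. Since the groups lay on different slides, slide cannot be told apart from washout for a single gene.

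The comparison of washout with control asked which levels differed from control 48 h after removal. Immediate early genes, which respond quickly to growth signals, were higher: 9 of 13 rose and none fell, and 9 rose and 1 fell adjusted over the list alone (mean 0.89, adjusted p = 3.0e-07; adjusted p = 0.350 with an estimated correlation). The factors Egr1 and Egr2 rose by 2.38 ± 0.08 and 2.14 ± 0.07. Fos rose by 1.41 ± 0.07 on a probe in a bright region of a slide. Some Wnt targets were still higher, Sp5 by 2.02 ± 0.08 and Axin2 by 1.46 ± 0.13, while Apcdd1, a Wnt inhibitor, fell by 1.44 ± 0.11. Of 19 Wnt targets 6 rose and 4 fell, and 7 rose and 8 fell adjusted over the list alone, and the list did not pass (mean 0.17, median -0.03, adjusted p = 0.548).

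The lists of extracellular matrix genes and meningeal fibroblast markers passed the test as lower. Of 30 extracellular matrix genes 11 fell and 3 rose, and 18 fell and 3 rose adjusted over the list alone (mean -0.47, adjusted p = 7.8e-05; adjusted p = 0.723 with an estimated correlation), with Postn, a matricellular protein, at -2.35 ± 0.10 and Col3a1, a fibrillar collagen, at -1.46 ± 0.11. Markers of meningeal fibroblasts moved with them, 9 of 12 falling and 1 rising, also adjusted over the list alone (mean -0.96, adjusted p = 0.00020; adjusted p = 0.723 with an estimated correlation), with Foxd1 at -1.82 ± 0.18 and Lum at -1.53 ± 0.10. Col1a1, Col1a2, Col3a1, Dcn and Postn are in both lists. Of 18 interferon response genes 7 fell, and 13 adjusted over the list alone (mean -0.74, adjusted p = 2.2e-05; adjusted p = 0.723 with an estimated correlation), with Isg15 at -1.50 ± 0.19; 1 of 19 microglia markers fell and none rose. Of 8 pericyte and smooth muscle markers 5 fell, also adjusted over the list alone (mean -0.54, adjusted p = 0.0058; adjusted p = 0.602 with an estimated correlation). Of 7 oligodendrocyte precursor markers 3 fell, and 5 adjusted over the list alone (mean -0.53, adjusted p = 0.0019; adjusted p = 0.602 with an estimated correlation). Of 29 integrin and focal adhesion genes 6 fell and 2 rose, and 8 fell and 2 rose adjusted over the list alone (mean -0.24, adjusted p = 0.0098; adjusted p = 0.779 with an estimated correlation). The call for neural progenitor genes (mean -0.17, adjusted p = 0.039; adjusted p = 0.602 with an estimated correlation) was lost under most alternatives. None of 20 ribosomal protein genes and 1 of 9 ependymal markers passed the test, and adjusted over the list alone 4 ependymal markers were higher and 2 lower. Olfr1099, Zswim2, H2-T3 and Hecw1 passed the test as rises, on probes that all lie in a bright region of the washout slide.

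In limma 826 features were higher in washout than in control and 1213 lower, 180 and 257 of them at least 2-fold. These counts depended on single arrays: without control 1, control 2, Ro 1, Ro 2, washout 1 or washout 2 there were 178, 115, 258, 156, 487 and 1311 higher, and 508, 287, 365, 217, 507 and 905 lower. Of the calls 40.5% were higher, against 30.8% with median centring, 29.1% with the authors' values, 25.9% without control 1 and 59.2% without washout 2. There were 62 higher and 79 lower with no filter on dim probes, 296 and 469 with a replicate block, 392 and 577 with only the 4 arrays compared, and 1288 and 1308 higher with an intensity trend without and with robust fitting. Among lists that did not pass, mean and test differed in sign for Notch pathway genes, and mean and median for glycolysis genes. Age in culture and slide both differed between these groups.

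Most of the changes seen with Ro ran back after washout. The interferon response list, with a mean of -0.87 with Ro, did not pass in washout minus Ro (mean 0.13, adjusted p = 0.290). There 5 of its 18 genes rose and 2 fell, also adjusted over the list alone, and its mean in washout minus control was -0.74. In washout minus Ro, extracellular matrix genes did not pass either (mean -0.15, adjusted p = 0.540), with 6 of 30 higher and 9 lower. Nor did pericyte and smooth muscle markers (mean 0.22, adjusted p = 0.275), with 4 of 8 higher and 1 lower. Both lists had passed as lower with Ro and passed as lower in washout minus control, with means of -0.47 and -0.54 there. Of the 8487 features called in Ro minus control, 6174 (72.7%) were called in the opposite direction in washout minus Ro, and 1038 (12.2%) in the same direction in washout minus control. The median ratio of the change left after washout to the change with Ro was 0.124. These comparisons share arrays, and genes are not independent replicates. Sharing alone makes simulated unchanged groups correlate across genes at r = 0.499 for washout minus control with Ro minus control (0.247 in the data). For washout minus Ro with Ro minus control it gives r = -0.498 (-0.826 in the data). The Ro change widens the spread in the data, so that r there is not on the scale of the simulated r. In the same order, covariances were 0.0875 and -0.504 in the data, against 0.0171 and -0.0170 simulated. From contrasts that share no array, the retained fraction of the Ro change was 0.120 (0.136 and 0.105 for the 2 assignments of the controls). A shift of the washout slide unrelated to the Ro change would by itself leave this fraction near 1, and it would part washout from control as well as from Ro, while control and washout arrays correlated at 0.984 to 0.985 and Ro and washout arrays at 0.960 to 0.964. The values thus argue against such a shift as the whole cause of the return, not against a share of it in single genes. The share still called in the same direction was 1.33% with no filter on dim probes, 5.12% with only the 4 arrays compared, 5.88% with a replicate block and 6.89% for changes of at least 2-fold. It was 3.60% to 8.61% with 1 array left out: 5.96% without Ro 1, 3.60% without Ro 2, 7.78% without control 1, 4.71% without control 2, 5.37% without washout 1 and 8.61% without washout 2.

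**Figure D4:**
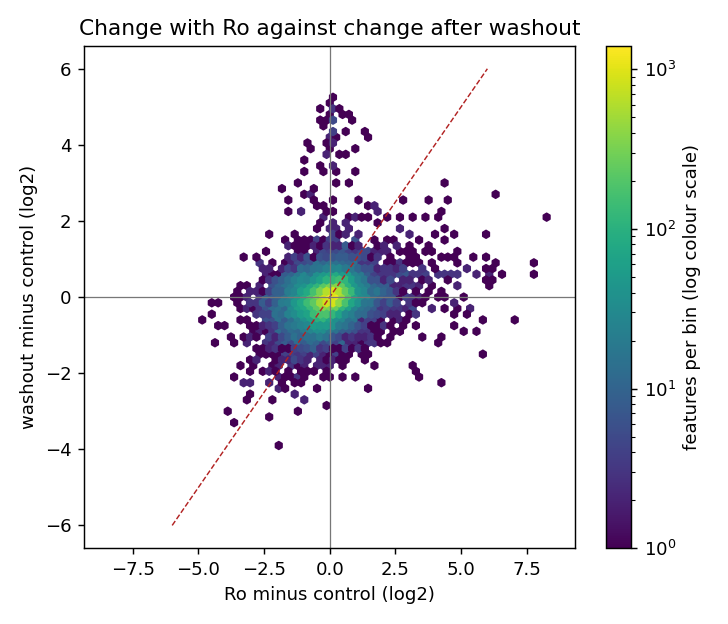
Log2 change of each of 20092 features in washout minus control (vertical) against Ro minus control (horizontal), as counts per hexagon on a log colour scale; the dashed line marks equal change. The median ratio of the vertical to the horizontal value over called features was 0.124; some features near 0 on the horizontal axis with a large rise lie in bright regions of the washout slide.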

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

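The tests of the bright region, the limit to genes in it and the reference set for other probes, and the tests of scaling for both gene lists and of a lasting loss of ciliated cells were chosen after the results they address were seen.

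Negative control spots, which match no mouse transcript and enter no comparison, were counted on each array, and 3 arrays had more well above background than either control array. Of 153 such spots there were 4 on Ro 1, 10 on washout 1 and 7 on washout 2, against 3 and 2 on the control arrays and 1 on Ro 2, so that the Ro arrays were not both above control. Of these, 6 on washout 1 and 2 on washout 2 lay in the bright regions described next, and none on the other arrays.

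On the washout slide, spots in bright regions numbered 1665 on washout 1 and 363 on washout 2, against 8 to 30 on the other arrays. Of 88 features dim in control and called higher in washout minus control, 52.27% lay in such a region, near the bound of 50% set for this test, against 4.92% of all tested features, so that the bright region may account for many of these calls. In washout minus Ro, 57 of 259 features dim in Ro and called higher lay in such a region. Expression of the genes would also raise their other probes. Of 7 such probes 0 (0%) were well above background on both washout arrays. The value was 37.9% of 491 other probes of features outside the regions in the same range of washout signal. The picked genes had no probe well above background in control, a condition not set for that reference. A reference also dim in control held 1 feature and 0 other probes. The comparison therefore cannot decide for or against expression. The test as planned, over the features outside the regions too, gave 0 of 11, and 0 of 4 for those outside, so that it does not separate the 2 sets. What raised the features outside the regions stays open.

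Ependymal markers fell with Ro and rose after washout. The mean nearest 0 over 4 other scalings was -1.455, so that the fall did not depend on the choice among them. These scalings put the median Ro change of all features between -0.023 and 0.047. They could hardly have removed the fall, so that a scaling error common to all of them was not tested. A lasting loss of ciliated cells is argued against by a mean of 0.2041 in washout minus control, although slide and age differed there. The ependymal list did not pass there (adjusted p = 0.130), with 4 of 9 markers higher and 2 lower adjusted over the list alone. Motile cilium genes outside the list had 8 of 26 higher and none lower there, and 12 and 1 adjusted over the list alone (mean 0.35, adjusted p = 7.2e-06, and 0.537 with an estimated correlation). Motile cilium genes outside the list had a mean of -1.105 with Ro, 24 of 26 lower and 1 higher (adjusted p = 5.6e-10; adjusted p = 0.271 with an estimated correlation), so that a change across the motile cilium programme is a candidate explanation. Whether ciliated cells or transcripts per cell changed was not tested.

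Ribosomal protein genes rose with Ro. The smallest list mean over 4 other scalings was 0.5309, so that the rise did not depend on the choice among them. These scalings put the median Ro change of all features between -0.023 and 0.047. They could hardly have removed the rise, so that a scaling error common to all of them was not tested. A shift of all bright probes is argued against by a mean of -0.03162 in random lists matched on signal. None of 10000 such lists reached the list mean (highest 0.44). Of 56 ribosomal protein genes outside the list 51 (91.07%) were higher (adjusted p = 6.2e-14; adjusted p = 0.313 with an estimated correlation), so that a rise across this class is a candidate explanation. A labelling bias toward short transcripts was not tested and stays open.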

How the results depend on the processing

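The median-signal background correction, the exchanged pairing and the fit without bright regions were chosen after seeing the data. The planned correction on the mean spot signal was not run, since the files lack that column. Signal over background limits the dim features. Without a filter 2497 features were higher in Ro minus control, 2699 lower in washout minus Ro, 62 higher and 79 lower in washout minus control, and 1.33% of Ro calls stayed in the same direction; more features were tested, and the median of all features in washout minus Ro was 0.14. An intensity trend gave 1288 higher in washout minus control and 1308 with robust fitting. With only the 4 arrays compared, washout minus control had 392 higher and 577 lower (5.12% staying), and with a replicate block 296 and 469 (5.88%). An exchanged pairing gave 734 and 955, and without bright regions there were 729 and 1197. At least 2-fold changes numbered 865 and 1398, 1323 and 989, and 180 and 257 in the 3 comparisons, with 6.89% staying. With 1 array left out, the lone array assumed to vary like the others, Ro minus control ranged over 1962 to 3972 higher and 2672 to 4607 lower, washout minus Ro over 2624 to 4638 and 2230 to 3636, and washout minus control over 115 to 1311 and 217 to 905. The share turning back ranged from 61.5% to 78.4%, the share staying from 3.60% to 8.61%, and the median ratio from 0.107 to 0.157. No list mean that had passed changed sign under these alternatives. Apart from Dsp, the genes that changed sign had not passed the test. In Ro minus control Slc1a3 was -0.028 with quantile normalization and Gsk3b -0.040 with the mean of probes, and in washout minus Ro Slc1a3 was 0.0075 with quantile normalization. In washout minus control, the median signal gave Ctnnb1 0.0046 and Slc1a3 0.019, quantile normalization gave Gsk3a -0.011, Ctnnb1 0.0053, Vim 0.026 and Rps14 0.014, median centring gave Gsk3a -0.031, the authors' values gave Gsk3a -0.044 and Gfap -0.0058, and the mean of probes gave Gfap -0.075, Slc1a2 -0.024 and Smo -0.094. With 1 array left out, Dsp, a called gene, went from -0.49 to 1.98 in Ro minus control, where the -0.49 (without control 2) came from another probe that became the highest; the probe used otherwise gave 0.79. Slc1a3 ranged from -0.024 to 0.14 there. In washout minus control the ranges were -0.028 to 0.0046 for Ctnnb1, -0.034 to 0.14 for Gfap, -0.13 to 0.16 for Gsk3a, -0.37 to 0.048 for Gsk3b, -0.056 to 0.28 for Hspa8, -0.15 to 0.013 for Rps14, -0.17 to 0.00067 for Rps20, -0.11 to 0.056 for Slc1a3, -0.00043 to 0.16 for Smo and -0.28 to 0.14 for Vim. Where no cause is named, the cause was not tested.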

Other observations

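The lists in this part were chosen after the main results were seen and before their own values, as 7 lists adjusted together, and the clock test was corrected after a first value was seen. Genes are named after their values were seen.

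Genes of axon and cell guidance went both ways with Ro: of 36 measured, 10 rose and 15 fell, and 10 rose and 18 fell adjusted over the list alone, with mean 0.04, median -0.28 and a test that did not pass (adjusted p = 0.165). The semaphorin Sema6a and the ephrin receptors Epha7 and Ephb1 rose by 2.05 ± 0.16, 1.97 ± 0.13 and 1.89 ± 0.10, while Sema3e and Sema3f fell by 1.97 ± 0.07 and 1.68 ± 0.13. Of 16 hypoxia response genes 9 fell and 3 rose, and 10 fell and 5 rose adjusted over the list alone, and the list did not pass (mean -0.39, adjusted p = 0.082).

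A rise of the amino acid response with Ro was proposed from Slc7a11, and 20 other genes had a mean of 0.3447, with 11 higher and 2 lower and 11 higher and 4 lower adjusted over the list alone (adjusted p = 0.045; adjusted p = 0.271 with an estimated correlation). The glutamine transporters Slc1a5 and Slc38a2 rose by 2.50 ± 0.10 and 1.37 ± 0.08. A rise of ribosome assembly genes was proposed from the ribosomal protein genes, and 19 nucleolar genes had a mean of 0.4499, with 14 higher and 16 adjusted over the list alone (adjusted p = 4.3e-06; adjusted p = 0.271 with an estimated correlation). Dkc1, Npm1 and Gnl3 rose by 0.79 ± 0.17, 0.76 ± 0.07 and 0.74 ± 0.07. Each stays a hypothesis, since it was proposed from the same data.

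Another phase of the circadian clock on the washout arrays was tested as the mean of Bmal1, Npas2 and Clock minus that of 6 opposing genes in washout minus control. A first version missed Bmal1, which the reference names Arntl, and came out near 0, on the side against the explanation. With Arntl and Clock, and Npas2 not measured, the difference was -0.3277, which lies between the bounds set beforehand, so that another clock phase could neither be told from none nor set aside. Slide and age also differed between these groups. Of 16 clock genes 1 rose and 6 fell with Ro, and 1 and 7 adjusted over the list alone (adjusted p = 0.082), and 5 were higher and 3 lower in washout minus control, and 6 and 4 adjusted over the list alone (adjusted p = 0.237). In washout minus Ro 6 rose and 1 fell, also adjusted over the list alone, and the list passed (adjusted p = 0.021; adjusted p = 0.154 with an estimated correlation).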
